A study of Rattus norvegicus with 9 samples.

How the data were processed

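RNA of 9 rat liver cell preparations was measured, 3 each of adult hepatocytes, OC.2- fetal cells and OC.2+ fetal cells, grouped by the sample titles. Per the labels' protocols, total RNA was extracted with the mirVana kit from freshly isolated cells, and 150 ng entered an Affymetrix whole-transcript amplification before hybridisation to 1 array per preparation. The deposited values are intensities on a linear scale. Partek 6.6 and RMA are named in the submitters' processing notes, with no role or order given. RMA as usually run makes the distributions of the arrays alike, which can remove a change shared by most genes. It also shrinks differences of dim genes. The deposited distributions were not fully alike, with higher medians on all fetal than on all adult arrays. The genome build and the annotation are not given in the sources used here. The table has 28826 rows. A probe annotation table gave 1 gene symbol to 15209 of them, several to 306 and none to 13311, and 15178 of the single symbols were found in a current table of rat genes (assembly GRCr8, used for names only), which changed 0 of them. Rows with several genes or none were not named.

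Log2 of each intensity was taken before any test. A gene with several probe sets (494 genes) was represented by the one with the highest mean over all arrays, which left 14497 genes, with no filter on dim genes and no detection call. Group means were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes over all 9 arrays, which share one estimate of the spread with 6 residual degrees of freedom, and p-values were adjusted with Benjamini and Hochberg's method over all genes. A gene was called at adjusted p under 0.05, and the number that also differed at least 2-fold is given beside each count. The tests were 2-sided. The comparisons were OC.2+ against OC.2- fetal cells, OC.2- fetal cells against adult hepatocytes and OC.2+ fetal cells against adult hepatocytes.

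Gene lists were fixed before the data were examined. They covered hepatocyte functions, growth, stress and signalling genes, markers of the cell types that a liver digest can hold, and sex-linked markers. Of the 34 lists, 33 had at least 2 measured members and were tested. The list left out was that of sex-linked markers, so a part of sex in the differences was not tested. Limma's camera with a preset correlation of 0.01 tested each list against all other genes, adjusted over the lists of a comparison. With the correlation estimated from the data, 12 of 25 list calls held in OC.2+ against OC.2- cells, 6 of 24 in OC.2- cells against adult hepatocytes and 13 of 23 in OC.2+ cells against adult hepatocytes. List counts are also given with p-values adjusted over the list alone. The genes to be named were chosen by a rule fixed at the same time. Among called genes whose arrays did not overlap between groups, the rule took the 8 highest and the 8 lowest log2 differences. From every list it took up to 2 called members each way. It added Lap3, Anpep, Lnpep, Alb, Afp, Krt19, Epcam and Hnf4a whatever their values, and Sox9, for which the array annotation used here names no single-gene probe set. Because this rule gave more than 30 genes per comparison, some list members were left out of the text. Those kept as examples were picked with their values known, without regard to direction.

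In simulated data of 14497 genes, 200 were changed by 0.5 or 1 log2 units, and the 31 DNA replication genes were also raised by 0.5. Of the 200, the fit recovered 87% of genes changed by 0.5 and 100% of those changed by 1 for OC.2+ against OC.2- cells, with 20 unchanged genes called. The values were 84% and 100% with 11 for OC.2- cells against adult hepatocytes, and 87% and 100% with 12 for OC.2+ cells against adult hepatocytes. The simulated noise was independent between genes, and far fewer genes were changed than the real comparisons called. Alternatives covered 3 other scalings (quantile normalization again, median centring and cyclic loess), a pair of filters on dim genes, the mean of probe sets, all rows of the table, a trended and robust variance, array weights, fits of only the groups compared, the replicate number as a block, a threshold of 0.01, other list tests, and leaving out each replicate in turn. Their effects are given in the closing section.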

Results

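Gene expression was measured in liver cells of F344 rats on Affymetrix Rat ST 1.0 arrays, 1 array for each of 9 RNA preparations. Hepatocytes of adult rats aged 5 to 6 weeks, released by collagenase perfusion, made up 1 group of 3 arrays. The other arrays held fetal liver cells of embryonic day 19 that had been dissociated with collagenase and immunopurified with an antibody to leucine aminopeptidase, a surface protein of hepatic cells, and an antibody to OC.2, which the submitters describe as a ductal marker. Of these, 3 arrays held cells that the labels name positive for both antigens (OC.2+) and 3 held cells named positive for leucine aminopeptidase and negative for OC.2 (OC.2-). The isolation text gives the same double positive selection for both fetal groups, and short descriptions of the OC.2+ samples read LAP-OC2+, so the division into OC.2+ and OC.2- rests on the titles and the cell type labels. The labels call the 3 preparations of each group biological replicates. Median intensity per array was 79.5 to 81.0 for adult hepatocytes and 86.5 to 89.7 for the fetal cells, so it differed along the comparisons with adult hepatocytes. Correlations of log2 intensity between arrays of 1 group were 0.988 to 0.991 for adult hepatocytes, 0.986 to 0.991 for OC.2- cells and 0.991 to 0.992 for OC.2+ cells. Between groups they were 0.928 to 0.939 for OC.2+ with OC.2- cells, 0.902 to 0.916 for OC.2- cells with adult hepatocytes and 0.829 to 0.840 for OC.2+ cells with adult hepatocytes. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.095. Levels are given as mean log2 intensity ± SD (n = 3), differences as folds with 95% intervals or as log2 differences ± SE, and adjusted p-values come from limma. For gene lists they come from camera, and list medians are medians of log2 differences. For each gene described as higher or lower, all 3 arrays of one group lay above all 3 of the other, which chance gives for 10% of genes.

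The first comparison set the fetal cells with OC.2 against those without it. Genes of granulocytes and of red-cell precursors were far higher in the OC.2+ cells, and complement and coagulation genes and liver transcription factors were lower. Ngp, a neutrophil granule protein, was 93.8-fold (95% interval 80.1 to 109.8) higher, and Mpo, the myeloperoxidase of neutrophil granules, 44.6-fold (95% interval 38.1 to 52.2) higher. Hnf4a, a transcription factor central to hepatocyte identity, was 6.06-fold (95% interval 5.24 to 7.01) lower, and Lyve1, a marker of sinusoidal endothelium, 8.84-fold (95% interval 7.31 to 10.7) lower. The biliary keratin Krt19 was 1.47-fold (95% interval 1.28 to 1.69) lower in the OC.2+ cells. Epcam, an epithelial adhesion molecule of biliary cells, differed by -0.10 ± 0.09 on the log2 scale (adjusted p = 0.462). Both were dim: log2 intensity was 5.556 to 6.624 for Krt19 and 5.487 to 5.917 for Epcam over the 9 arrays. The medians of these arrays were 6.31 to 6.49. With no detection call, folds of these genes, here and against adult hepatocytes, cannot show whether either was expressed.

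On the granulocyte list 22 of the 24 measured genes rose (22 adjusted over the list alone), median 3.05, adjusted p = 2.22e-19. Besides Ngp and Mpo, the defensin gene Defa5 was 60.3-fold higher, Prg2, the major basic protein of eosinophils, 54.2-fold higher and S100a9, a calcium-binding protein of neutrophils, 39.5-fold higher. Lyz2 (lysozyme) was 60.2-fold higher, Nkg7, a granule protein of cytotoxic lymphocytes, 40.9-fold higher and Lypd8l1 65.4-fold higher. On the erythroid list 28 of the 30 genes rose (1 fell, 28 higher and 1 lower adjusted over the list alone, median 1.69, adjusted p = 1.51e-15). Carbonic anhydrase Car1 was 5.6-fold higher, and the embryonic globin Hbe1 was 3.46-fold lower. Megakaryocyte and platelet genes rose in 12 of the 16 cases (12 adjusted over the list alone, median 0.93, adjusted p = 5.4e-08). Among them Gfi1b, a transcriptional repressor needed for erythroid and megakaryocytic development, was 5.13-fold higher. Of the 21 measured mast cell and blood progenitor genes, 13 rose and 5 fell (13 and 5 adjusted over the list alone, median 0.87, adjusted p = 0.00302, adjusted p = 0.074 with an estimated correlation). The leukocyte tetraspanin Cd53 was 5.9-fold higher, and Hdc, which makes histamine, was 5.69-fold lower. Of the 23 measured macrophage genes, 7 rose and 7 fell (7 and 8 adjusted over the list alone). Their median was -0.11 and their mean 0.47, and camera pointed up at adjusted p = 0.797. Cybb, a subunit of the phagocyte oxidase, was 6.44-fold higher, and the mannose receptor Mrc1 was 2.46-fold lower.

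**Figure D1:**
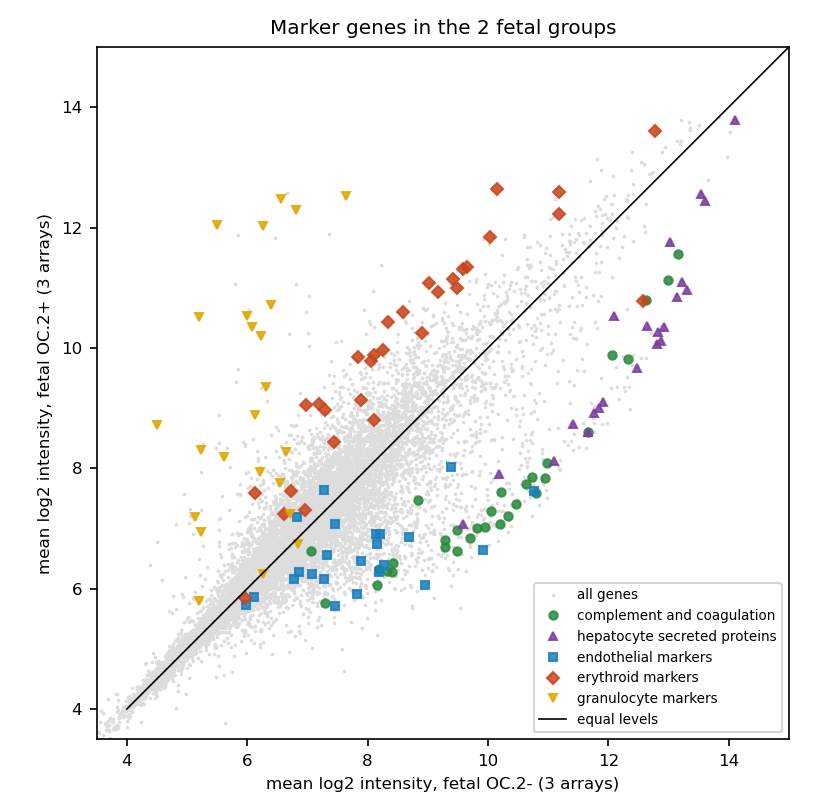
Mean log2 intensity of each gene in OC.2- cells (x axis) and OC.2+ cells (y axis), 3 arrays each; small grey dots are all genes tested, coloured symbols are members of 5 gene lists, and the line marks equal levels. Most granulocyte and erythroid genes lie above the line (median log2 differences 3.05 and 1.69), while secreted-protein (-2.53), complement and coagulation (-2.61) and endothelial genes (-1.30) lie mostly below it.

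On the same arrays, all 22 measured genes of secreted plasma proteins fell (22 adjusted over the list alone, median -2.53, adjusted p = 6.32e-23, adjusted p = 0.0539 with an estimated correlation). Prothrombin F2 was 8.4-fold lower, Hrg, a histidine-rich plasma glycoprotein, 10.6-fold lower and Proz, a vitamin K-dependent plasma protein, 11.4-fold lower. Albumin, near the top of the intensity range, was 1.25-fold lower and alpha-fetoprotein (Afp) 1.82-fold lower. All 31 complement and coagulation genes fell (31 adjusted over the list alone, median -2.61, adjusted p = 2.49e-29). Of the liver transcription factors 18 of the 21 fell (18 adjusted over the list alone, median -1.37, adjusted p = 3.6e-11), and Ppara, the fatty-acid-sensing nuclear receptor, was 6.15-fold lower. Genes of the urea cycle and amino acid catabolism fell in 25 of the 30 cases (2 rose, 25 lower and 2 higher adjusted over the list alone, median -1.89, adjusted p = 8.52e-16, adjusted p = 0.0539 with an estimated correlation). The urea cycle enzyme Otc was 9.71-fold and the methyltransferase Bhmt 10.4-fold lower. Of the 15 measured gluconeogenesis and glycogen genes, 1 rose and 14 fell (1 and 14 adjusted over the list alone, median -1.37, adjusted p = 1.13e-10, adjusted p = 0.0539 with an estimated correlation), and liver glycogen synthase Gys2 was 11-fold lower. Fatty acid oxidation genes fell in 21 of the 23 cases (21 adjusted over the list alone, median -1.53, adjusted p = 3.28e-15, adjusted p = 0.0539 with an estimated correlation). Cholesterol synthesis genes fell in 19 of the 21 (19 lower and 1 higher adjusted over the list alone, median -1.43, adjusted p = 1.28e-12, adjusted p = 0.0539 with an estimated correlation). Bile acid genes fell in 17 of the 21 (17 adjusted over the list alone, median -1.25, adjusted p = 7.7e-11). Phase I enzymes fell in 18 of the 35 (18 adjusted over the list alone, median -0.33, adjusted p = 4.51e-07) and phase II enzymes in 15 of the 25 (15 adjusted over the list alone, median -0.78, adjusted p = 2.55e-08). Fmo1, a flavin monooxygenase of drug metabolism, was 8.86-fold lower, and the hydrolase Cmbl 11.1-fold lower.

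Imprinted growth genes were lower as a group in the OC.2+ cells: 15 of the 16 fell (15 adjusted over the list alone, median -1.71, adjusted p = 1.03e-12), with Mest 10.2-fold and the fetal growth factor Igf2 6.5-fold lower. Of the 14 measured fetal liver and hepatoblast genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone, median -0.52, adjusted p = 0.000213, adjusted p = 0.0539 with an estimated correlation). The heparan sulphate proteoglycan Gpc3 was 8.81-fold lower and the chromatin protein Hmga1 1.69-fold higher. Endothelial genes fell in 19 of the 23 cases (2 rose, 19 lower and 2 higher adjusted over the list alone, median -1.30, adjusted p = 1.69e-10, adjusted p = 0.0944 with an estimated correlation). Gpr182, a receptor of sinusoidal endothelium, had the lowest log2 difference of any gene named (-3.85 ± 0.16). Stellate and mesenchymal genes fell in 20 of the 27 (23 adjusted over the list alone, median -0.55, adjusted p = 7.23e-09, adjusted p = 0.0699 with an estimated correlation), among them the matrix proteoglycan Dcn at 10.4-fold. Of the 22 measured ductal and progenitor genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone, median -0.10, adjusted p = 0.153). The list passed with fry, which tests it against no change (adjusted p = 2.19e-05, range over the alternatives 2.19e-05 to 0.231). Prom1, a progenitor surface protein, was 1.95-fold higher, and Bicc1, an RNA-binding protein of tubular epithelia, 2.9-fold lower. Of the aminopeptidases that carry or have carried the name of the sorting antigen, Lap3 was 3.36-fold and Anpep 2.63-fold lower in OC.2+ cells and Lnpep 1.43-fold higher. Which of them the antibody binds is not given in the sources used here.

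Together with the blood-cell genes, DNA replication genes rose in 30 of the 31 cases (31 adjusted over the list alone, median 1.01, adjusted p = 2.55e-14), and the polymerase clamp Pcna was 3.18-fold higher. Mitosis genes rose in all 29 cases (29 adjusted over the list alone, median 0.94, adjusted p = 4.25e-13, adjusted p = 0.102 with an estimated correlation), and the mitotic kinase Plk1 was 2.81-fold higher. In all, 2944 of 14497 genes were higher and 2632 lower in OC.2+ than in OC.2- cells at limma adjusted p under 0.05, of which 535 and 961 differed at least 2-fold. Higher genes were 52.8% of those called on the deposited values, 52.3% after quantile normalization, 52.2% after median centring and 45.2% after cyclic loess (2514 higher and 3052 lower). The 3 arrays of each group did not overlap for 46.5% of genes. Folds of genes near the bottom or the top of the intensity range can be understated, and close relatives such as Hbb and Hbb-b1, the defensins and the Cyp2c enzymes can share probe signal.

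**Figure D2:**
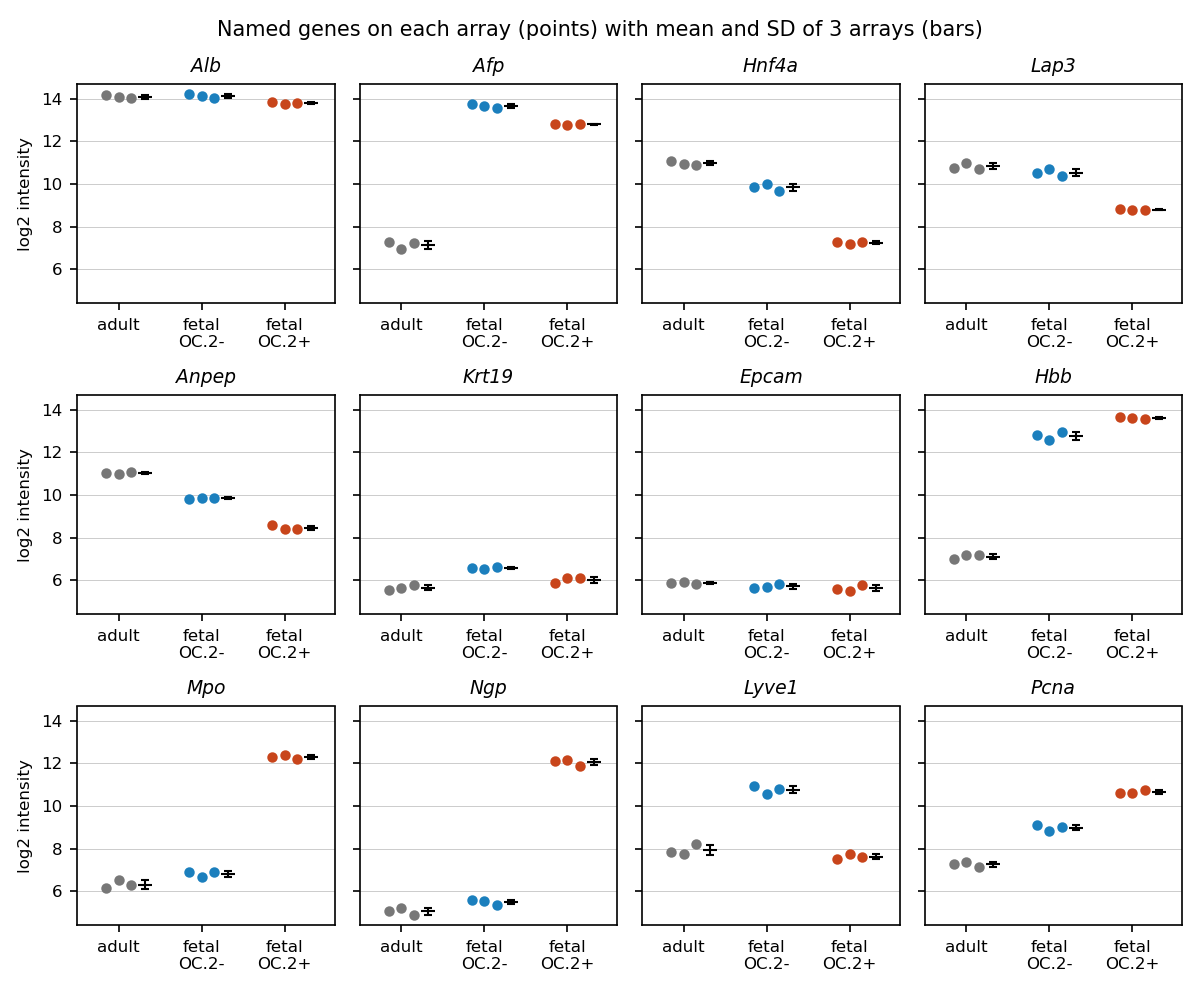
Log2 intensity of 12 genes on each array (points) in adult hepatocytes, OC.2- and OC.2+ fetal cells, with the mean and SD of 3 arrays (bars). Mpo and Ngp were high in the OC.2+ cells (12.30 ± 0.08 and 12.05 ± 0.14), Lyve1 in the OC.2- cells (10.76 ± 0.18), and Hnf4a was lowest in the OC.2+ cells (7.24 ± 0.06).

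The second comparison set the OC.2- fetal cells against adult hepatocytes. Fetal liver and hepatoblast genes and erythroid genes were higher in the fetal cells, and phase I and phase II enzymes were lower. H19, an imprinted non-coding RNA, was 154-fold (95% interval 122 to 195) higher, Afp 91.7-fold (95% interval 79.4 to 106) higher and the embryonic globin Hbe1 103-fold (95% interval 90.6 to 117) higher. Cyp2c11, a steroid-hydroxylating P450 of adult rat liver, was 237-fold (95% interval 202 to 279) lower, and tyrosine aminotransferase (Tat) 119.6-fold (95% interval 104 to 138) lower. Albumin was 14.11 ± 0.08 in the fetal cells and 14.09 ± 0.09 in adult hepatocytes, a difference of 0.02 ± 0.08 (adjusted p = 0.855). It depended on the scaling, at -0.29 after quantile normalization (adjusted p = 0.0029), -0.11 after median centring (adjusted p = 0.35) and -0.50 after cyclic loess (adjusted p = 6.8e-05).

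The fetal liver and hepatoblast list rose in 13 of the 14 cases (13 adjusted over the list alone, median 1.77, adjusted p = 1.03e-09). Of the 16 measured imprinted growth genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone, median 2.47, adjusted p = 5.3e-08, adjusted p = 0.071 with an estimated correlation). Igf2 was 87.5-fold higher and the amino acid transporter Slc38a4 9.8-fold lower. The protease inhibitor A2m was 70.2-fold higher. Phase I enzymes fell in 33 of the 35 cases (1 rose, 33 lower and 1 higher adjusted over the list alone, median -3.29, adjusted p = 1.01e-26). Cyp2c13 was 184-fold lower and Fmo1 2.46-fold higher. The steroid dehydrogenase Hsd3b5 was 96.8-fold lower, the dehydrogenase Dhrs7l1 117-fold lower and the protease inhibitor Serpina3c 108-fold lower. Of the 25 measured phase II enzymes, 2 rose and 21 fell (2 and 21 adjusted over the list alone, median -1.56, adjusted p = 1.21e-11). The sulfotransferase Sult1c3 was 70.8-fold lower and the glutathione transferase Gstp1 5.22-fold higher. Bile acid genes fell in 19 of the 21 cases (2 rose, 19 lower and 2 higher adjusted over the list alone, median -2.83, adjusted p = 1.76e-14), among them Cyp8b1, which makes the cholic acid precursor, at 14.2-fold. In the urea cycle and amino acid catabolism 28 of the 30 fell (1 rose, 28 lower and 1 higher adjusted over the list alone, median -1.55, adjusted p = 7.07e-18, adjusted p = 0.071 with an estimated correlation), and tryptophan dioxygenase Tdo2 was 92.5-fold lower. Gluconeogenesis and glycogen genes fell in 13 of the 15 cases (2 rose, 13 lower and 2 higher adjusted over the list alone, median -0.78, adjusted p = 1.43e-06, adjusted p = 0.121 with an estimated correlation). Pck1 and G6pc1, which commit carbon to glucose, were 30.1-fold and 27.4-fold lower, while Gys2 was 3.31-fold higher. Fatty acid oxidation genes fell in 20 of the 23 cases (1 rose, 20 lower and 2 higher adjusted over the list alone, median -0.93, adjusted p = 1.33e-11, adjusted p = 0.115 with an estimated correlation), with the rate-setting transferase Cpt1a 13.6-fold lower.

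Of the 22 measured secreted-protein genes, 1 rose and 13 fell (1 and 13 adjusted over the list alone, median -0.43, adjusted p = 5.93e-05, adjusted p = 0.332 with an estimated correlation). Apolipoprotein Apoc3 was 5.28-fold lower and Apoa1 1.62-fold higher. Complement and coagulation genes fell in 28 of the 31 cases (2 rose, 28 lower and 2 higher adjusted over the list alone, median -0.82, adjusted p = 1.4e-12, adjusted p = 0.121 with an estimated correlation). C9 of the membrane attack complex was 9.98-fold lower and the kininogen Kng1 2.08-fold higher. Of the 21 measured liver transcription factors, 2 rose and 16 fell (2 and 16 adjusted over the list alone, median -1.06, adjusted p = 2.91e-07, adjusted p = 0.0711 with an estimated correlation), and Hnf4a was 2.2-fold lower. Of the 21 measured cholesterol synthesis genes, 4 rose and 10 fell (4 and 10 adjusted over the list alone), and camera missed the threshold (adjusted p = 0.0563), passing it without adult replicate 2 (adjusted p = 0.0257) or OC.2- replicate 2 (adjusted p = 0.0173). Sqle, an early enzyme of the sterol branch, was 1.99-fold higher.

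Erythroid genes rose in 27 of the 30 cases (1 fell, 27 higher and 1 lower adjusted over the list alone, median 1.94, adjusted p = 2.46e-16), with the haemoglobin chaperone Ahsp 82.7-fold and the beta-globin gene Hbb 50.6-fold higher. Endothelial genes rose in 21 of the 23 (21 adjusted over the list alone, median 1.48, adjusted p = 1.86e-10, adjusted p = 0.121 with an estimated correlation), with Lyve1 7.05-fold higher. Of the 27 measured stellate and mesenchymal genes, 22 rose and 1 fell (23 and 1 adjusted over the list alone, median 0.71, adjusted p = 9.28e-08, adjusted p = 0.115 with an estimated correlation), with Dcn 20.2-fold and the mesenchymal filament Vim 17.2-fold higher. Of the 23 measured macrophage genes, 16 rose and 4 fell (18 and 4 adjusted over the list alone, median 1.20, adjusted p = 0.000121, adjusted p = 0.215 with an estimated correlation). Mast cell and progenitor genes rose in 15 of the 21 (15 adjusted over the list alone, median 0.55, adjusted p = 6.18e-06), 8 of them at least 2-fold. Hdc, at 105-fold, lay far above the list median. Log2 intensity of Cpa3 was 6.823 to 7.305 on the OC.2- and 4.891 to 5.164 on the adult arrays. That of Mcpt8 was 4.269 to 4.78 and 4.29 to 4.816, so Hdc does not stand for the list. Megakaryocyte genes rose in 9 of the 16 (10 adjusted over the list alone, median 0.45, adjusted p = 0.00498, adjusted p = 0.072 with an estimated correlation). Granulocyte genes rose in 12 of the 24 (12 adjusted over the list alone, median 0.26, adjusted p = 0.02, adjusted p = 0.325 with an estimated correlation), and this call ended without OC.2- replicate 3 (adjusted p = 0.0577). Of the 22 measured ductal and progenitor genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.00209, adjusted p = 0.0583 with an estimated correlation). Krt19 was 1.9-fold and Bicc1 3.11-fold higher, and Epcam differed by -0.15 ± 0.09 (adjusted p = 0.211). Epcam passed after quantile normalization (adjusted p = 0.0226), median centring (0.0252) and cyclic loess (0.0301). DNA replication genes rose in 29 of the 31 cases (30 adjusted over the list alone, median 0.91, adjusted p = 2.12e-12, adjusted p = 0.0623 with an estimated correlation), with the helicase subunit Mcm2 3.8-fold higher. Mitosis genes rose in all 29 (29 adjusted over the list alone, median 1.04, adjusted p = 2.12e-12, adjusted p = 0.121 with an estimated correlation). Anpep was 2.25-fold lower and Lap3 1.23-fold lower. Lnpep went the other way, with log2 intensities of 6.71 to 6.868 on the OC.2- arrays and 6.192 to 6.351 on the adult arrays. The call for Lap3 (adjusted p = 0.0335) ended without adult replicate 2 (adjusted p = 0.13), OC.2- replicate 1 (0.0784) or OC.2- replicate 3 (0.128), and after quantile normalization (0.614).

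Across all genes, 3431 were higher and 3027 lower in OC.2- cells than in adult hepatocytes (limma adjusted p under 0.05), and 588 and 954 of these differed at least 2-fold. The share of higher genes among those called depended on the scaling between arrays. It was 53.1% on the deposited values, 47.7% after quantile normalization, 34.6% after centring each array on its median and 42.5% after cyclic loess. The median log2 difference of all genes was 0.066, -0.013, -0.063 and -0.018 in that order. Camera tests each list against the other genes, but its results still depended on the scaling. For immediate early and heat shock genes in this comparison, camera adjusted p went from 0.0563 to 0.0133 after median centring. Over all comparisons, 96 list results kept their direction and their side of the threshold after median centring. Of the others, 1 gained the call, 1 lost it and 1 turned.

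The third comparison set the OC.2+ fetal cells against adult hepatocytes. Erythroid and granulocyte genes were higher in the OC.2+ cells, and phase I enzymes were lower. Ahsp was 220.0-fold (95% interval 170.4 to 284) higher, Ngp 127-fold (95% interval 109 to 149) higher and Hbb 90.3-fold (95% interval 77.9 to 105) higher. Cyp2c11 was 205-fold (95% interval 174 to 241) lower, and the protease inhibitors Mug1 and Serpina3n were 139.9-fold and 135-fold lower. Cyp2c13 was 196-fold, Mug1l1 127-fold, Serpina3c 125-fold and Dhrs7l1 115-fold lower. Afp was 50.3-fold (95% interval 43.6 to 58.1) higher and albumin 1.23-fold (95% interval 1.09 to 1.39) lower.

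All 30 measured erythroid genes rose (30 adjusted over the list alone, median 3.69, adjusted p = 7e-18). Granulocyte genes rose in 23 of the 24 cases (23 adjusted over the list alone, median 3.14, adjusted p = 8.97e-14), with Defa5 75.2-fold, Prg2 69.9-fold, Mpo 63.2-fold and Lypd8l1 96.7-fold higher. The globin gene Hbb-b1 was 72.6-fold higher. Megakaryocyte genes rose in 15 of the 16 cases (15 adjusted over the list alone, median 1.35, adjusted p = 1.65e-06). Mast cell and progenitor genes rose in 20 of the 21 (1 fell, 20 higher and 1 lower adjusted over the list alone, median 1.38, adjusted p = 1.04e-07). Of the 23 measured macrophage genes, 17 rose and 3 fell (18 and 3 adjusted over the list alone, median 0.99, adjusted p = 0.000939, adjusted p = 0.29 with an estimated correlation). Cybb was 14.4-fold higher and Vsig4, a complement receptor of Kupffer cells, 2.44-fold lower. Replication genes rose in all 31 cases (31 adjusted over the list alone, median 1.84, adjusted p = 3.15e-14). Mitosis genes rose in all 29 (29 adjusted over the list alone, median 2.02, adjusted p = 9.51e-14, adjusted p = 0.122 with an estimated correlation). Pcna was 10.6-fold higher and cyclin Ccne1 9.34-fold higher. Fetal liver and hepatoblast genes rose in 12 of the 14 (12 adjusted over the list alone, median 1.25, adjusted p = 2.43e-05), with H19 51.3-fold higher. Of the 16 measured imprinted growth genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone, median 0.51, adjusted p = 0.0438, adjusted p = 0.363 with an estimated correlation). This call ended without the members shared with other lists (adjusted p = 0.461), without OC.2+ replicate 1 (0.0572) and without OC.2+ replicate 3 (0.0518).

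Every measured gene of several hepatocyte lists was lower in the OC.2+ cells than in adult hepatocytes, on arrays that also carried the blood-cell transcripts. This held for all 35 phase I enzymes (35 adjusted over the list alone, median -4.29, adjusted p = 1.13e-25). It held for all 30 genes of the urea cycle and amino acid catabolism (30 adjusted over the list alone, median -3.55, adjusted p = 4.39e-23) and all 31 complement and coagulation genes (31 adjusted over the list alone, median -3.66, adjusted p = 2.08e-24). It also held for all 22 secreted proteins (22 adjusted over the list alone, median -2.95, adjusted p = 1.37e-17, adjusted p = 0.078 with an estimated correlation). The same was true of all 21 liver transcription factors (21 adjusted over the list alone, median -2.29, adjusted p = 3.51e-13) and all 23 fatty acid oxidation genes (23 adjusted over the list alone, median -2.74, adjusted p = 2.45e-17, adjusted p = 0.0532 with an estimated correlation). Bile acid genes fell in 19 of the 21 cases (1 rose, 19 lower and 1 higher adjusted over the list alone, median -3.99, adjusted p = 1.08e-14), with the bile salt importer Slc10a1 50.1-fold lower. Gluconeogenesis genes fell in 14 of the 15 (14 adjusted over the list alone, median -2.66, adjusted p = 3.84e-11, adjusted p = 0.0564 with an estimated correlation). Phase II enzymes fell in 21 of the 25 (1 rose, 21 lower and 1 higher adjusted over the list alone, median -3.52, adjusted p = 1.97e-13). Cholesterol synthesis genes fell in 19 of the 21 (19 adjusted over the list alone, median -1.31, adjusted p = 1.46e-10, adjusted p = 0.078 with an estimated correlation). Hnf4a was 13.4-fold lower and the bile acid receptor Nr1h4 13.6-fold lower. G6pc1 was 57.4-fold lower and C9 40.9-fold lower.

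Of the 23 measured endothelial genes, 4 rose and 4 fell (4 and 3 adjusted over the list alone). Their median was 0.05 and their mean 0.02, and camera pointed down at adjusted p = 0.883, a direction that turned under other settings. Kdr, a receptor for vascular endothelial growth factor, was 2.14-fold lower and the transcription factor Erg 2.15-fold higher. Of the 27 measured stellate and mesenchymal genes, 8 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.12, adjusted p = 0.46). This list passed with fry (adjusted p = 0.0172, range over the alternatives 0.0172 to 0.772). Vim was 20.2-fold higher and the growth factor receptor Pdgfrb 3.01-fold lower. Of the 22 measured ductal and progenitor genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone, median 0.29, adjusted p = 0.0943), and the list passed with fry (adjusted p = 1.95e-07, range over the alternatives 1.95e-07 to 0.16). Prom1 was 4.07-fold higher. Krt19 was 1.29-fold higher, which no longer passed after quantile normalization (adjusted p = 0.0628) or cyclic loess (adjusted p = 0.0617). Epcam was 1.19-fold lower (adjusted p = 0.0349), a call that ended without adult replicate 1 or 2 (adjusted p = 0.0753 and 0.0928) and without OC.2+ replicate 1 or 2 (0.0817 and 0.146). Anpep was 5.93-fold and Lap3 4.11-fold lower, and Lnpep was 2.08-fold higher.

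**Figure D3:**
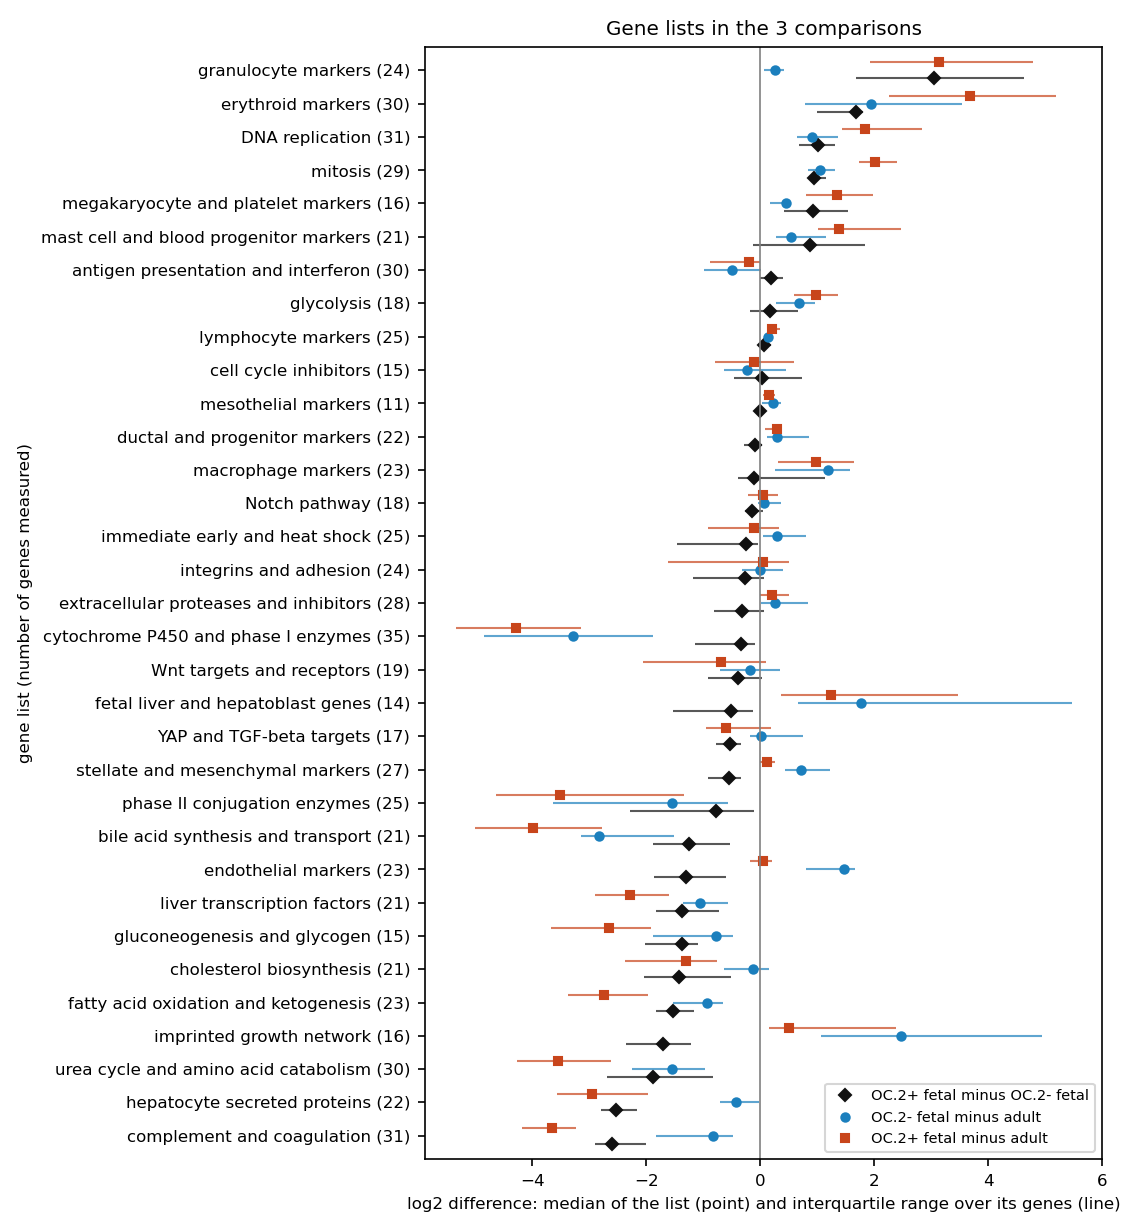
Median log2 difference (point) and interquartile range over the measured genes (line) of each gene list for the 3 comparisons, with the number of genes measured in brackets. In OC.2+ against OC.2- cells the medians ran from -2.61 for complement and coagulation to 3.05 for granulocyte markers, and phase I enzymes were low in both fetal groups against adult hepatocytes (-3.29 and -4.29).

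In total 4643 genes were higher and 3391 lower in OC.2+ cells than in adult hepatocytes (limma adjusted p under 0.05), and 1133 and 1616 of these differed at least 2-fold. Higher genes were 57.8% of those called on the deposited values, 50.2% after quantile normalization, 42.5% after median centring and 42.2% after cyclic loess. The median log2 difference of all genes was 0.108, 0.0037, -0.027 and -0.028 in that order.

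The change that both fetal groups shared against adult hepatocytes was examined last. Against the same adult arrays, 2627 genes were higher in both fetal groups and 2491 were lower in both, H19, Afp and Ahsp among the former and Cyp2c11, Car3 and Tat among the latter. Opposite calls were made for 169 genes higher in OC.2- and lower in OC.2+ cells and 112 the other way. Car3, a muscle-type carbonic anhydrase also abundant in adult liver, was 165-fold lower in OC.2- and 167-fold lower in OC.2+ cells. Independent lists of these sizes would share 1099 and 708 genes, and 100 simulations of unchanged groups against the adult arrays gave 0 at most. Those simulations hold no effects, so they do not show how much overlap the shared controls add. Fold changes of the 2 comparisons correlated across genes, which are not independent replicates, at r = 0.80, against 0.50 in the simulations, and their covariance was 0.696 against a simulated 0.00528, a difference of 0.690. With 3 adult arrays the controls could not be split into parts of 2 arrays, so part of the excess in overlap may come from the shared controls.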

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

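Both tests of the granulocyte and erythroid genes in this part were chosen only after the result was seen, and those of the hepatocyte genes before. A total of 13 genes were at least 2-fold higher than adult hepatocytes in one fetal group and at least 2-fold lower in the other. Each of these genes also passed limma's adjusted threshold between the fetal groups, but their selection made that nearly certain, so it adds no support. Higher in OC.2- and lower in OC.2+ cells were 12 of them, among them the endothelial receptor genes Gpr182 (log2 differences 2.84 and -1.02) and Kdr (1.80 and -1.10) and the hepatocyte genes Gys2 (1.73 and -1.74), Fmo1 (1.30 and -1.85) and Aqp9, a glycerol channel (1.66 and -1.26). The others were Tspan7, Adgrf5, Cldn1, B3galt1, Bmp2, Dnase1l3 and Prtfdc1. The reverse held for 1 gene, Lyz2 (-1.15 in OC.2- and 4.76 in OC.2+ cells). Tspan7, Adgrf5, Cldn1, B3galt1, Bmp2, Aqp9, Dnase1l3 and Prtfdc1 were named after their values were seen.

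Of the 13311 rows of the array table with no listed gene, which enter the comparisons only where all rows of the table were tested as an alternative, 397 changed at least 2-fold between the fetal groups, 567 between OC.2- cells and adult hepatocytes and 1018 between OC.2+ cells and adult hepatocytes.

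All 22 secreted-protein genes and all 31 complement and coagulation genes were lower in OC.2+ than in OC.2- cells. The median of the secreted-protein list was -2.54 or lower under median centring and cyclic loess, and further scaling did not end the fall. Both scalings were applied to the deposited values and cannot undo the authors' own, so this test does not exclude the authors' scaling as a cause. If OC.2+ preparations held the same hepatocytes diluted by other cells, metabolic hepatocyte genes would fall as far as secreted-protein and complement genes of like level. At middle levels the median of 16 metabolic genes was -3.05. This lay inside the 10th to 90th percentile of 21 secreted-protein and complement genes (-3.13 to -2.27, median -2.85 or 7.23-fold lower). Of the 16 genes, 9 lay inside that range, and all ran from -3.37 to -1.23. The median leaves dilution possible at these levels, though the single genes did not all fall alike. In contrast, 8 genes above log2 13, near the top of the range, fell by a median of 1.43. Lower expression per cell in the OC.2+ fraction is a biological alternative that was not tested and stays open.

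Granulocyte and erythroid genes were higher in OC.2+ than in OC.2- cells. A smaller share of hepatocytes as the whole cause would raise the markers of every other cell type alike. The endothelial list instead had a median of -1.30 (interquartile range -1.86 to -0.60), and 19 of its 23 genes fell while 2 rose. Its camera call (adjusted p = 1.69e-10) did not hold with an estimated correlation (adjusted p = 0.0944). The fall of most of these genes argues against an equal rise of every other cell type. It does not bear on a smaller share of hepatocytes with unequal changes of the other cell types. Blood-forming cells carried into the OC.2+ fraction cannot be told apart from transcription of these genes in the sorted hepatic cells: the rise of 92.6% of the erythroid and granulocyte genes (50 of 54) is the pattern itself and decides nothing between them. Both stay open, and Hbe1 went the other way (log2 -1.79 ± 0.08).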

How the results depend on the processing

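Across the alternatives, 5887 values of named genes kept their direction and their side of the threshold, 66 lost the call, 3 gained one and 5 turned, all of the last for Alb. For lists 1102 kept both, 49 lost the call, of which 41 with an estimated correlation, 28 gained it, 19 of them with fry, which by construction tests a list against no change, and 9 turned. Counts of called genes stayed within 1.5 times the main count in 215 cases and left that range in 9. After median centring 2139 genes were higher in OC.2- cells and 3024 in OC.2+ cells than in adult hepatocytes, and 3066 in OC.2+ cells after cyclic loess, and the cause was not tested beyond the shift of all genes given above. Testing all rows of the table, with more features by construction, gave 5783 higher in OC.2- cells (923 at least 2-fold) and 8223 in OC.2+ cells (1827 at least 2-fold). With a 2-fold threshold, 354 genes were higher and 853 lower in both fetal groups, a stricter criterion by construction. Alb in OC.2- cells against adult hepatocytes was -0.29 after quantile normalization (adjusted p = 0.0029), -0.11 after median centring (0.35), -0.50 after cyclic loess (6.8e-05) and -0.0207 to 0.0697 when replicates were left out, and the cause was not tested. Camera's direction turned, with no call and the cause not tested, for macrophage markers between the fetal groups (list medians -0.19 to -0.0385 when replicates were left out), for integrins in OC.2- cells against adult hepatocytes (-0.13 after median centring, -0.037 after cyclic loess, -0.0609 to 0.0153 when replicates were left out) and for endothelial markers in OC.2+ cells against adult hepatocytes (-0.099 after cyclic loess, 0.048 with fry, 0.0388 to 0.0865 when replicates were left out). Leaving out a replicate gave 2620 to 2867 higher genes in OC.2+ against OC.2- cells, 2862 to 3253 in OC.2- cells against adult hepatocytes and 4025 to 4373 in OC.2+ cells against adult hepatocytes. With the replicate number as a block, 2843 genes were higher and 2573 lower in OC.2+ against OC.2- cells, and deviations of same-numbered arrays correlated at -0.226 to 0.106, and the best match had the same number for 1 of 3 replicates in OC.2+ against OC.2- cells, 0 in OC.2- cells against adult hepatocytes and 2 in OC.2+ cells against adult hepatocytes, so the numbers were not taken to pair the samples. The 6 arrays of a comparison allow 10 splits, of which 1, the real one, gave as many genes (5576, 6458 and 8034 for OC.2+ against OC.2- cells, OC.2- cells and OC.2+ cells against adult hepatocytes, highest other 0 in each), and 10 are too few for a share under 0.05. Signal over background limits folds of genes with intensities near the lowest, since no detection call was used.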

Other observations

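The ratio over all erythroid genes in this part was chosen only after the filtered result was seen. Of the 18 measured glycolytic genes, 8 rose and 5 fell (8 and 5 adjusted over the list alone) in OC.2+ against OC.2- cells, and the list missed the threshold (camera adjusted p = 0.107, 0.0494 after cyclic loess). Hk1, the hexokinase of blood and brain, was 4.04-fold higher and the glucose transporter Slc2a3 4.97-fold higher in OC.2+ cells, while Slc2a1 was 1.79-fold lower. Against adult hepatocytes 12 rose and 1 fell (15 and 1 adjusted over the list alone) in OC.2- cells (median 0.67, adjusted p = 1.43e-05, adjusted p = 0.115 with an estimated correlation). In OC.2+ cells 14 rose and 2 fell (16 and 2 adjusted over the list alone), with median 0.98, adjusted p = 9.86e-05, adjusted p = 0.126 with an estimated correlation. Glycolytic aldolase Aldoa was 3.94-fold higher in OC.2- cells. Of the 30 measured antigen presentation and interferon genes, 3 rose and 17 fell (3 and 17 adjusted over the list alone) in OC.2- cells against adult hepatocytes (median -0.50, adjusted p = 4.75e-05, adjusted p = 0.121 with an estimated correlation). In OC.2+ cells against adult hepatocytes 5 rose and 14 fell (5 and 15 adjusted over the list alone, median -0.20, adjusted p = 0.00362, adjusted p = 0.227 with an estimated correlation). Usp18, an interferon-induced protease, was 11.7-fold and 9.3-fold lower. Between the fetal groups 10 rose and 4 fell (11 and 4 adjusted over the list alone), with median 0.19, adjusted p = 0.212. Of the 25 measured immediate early and heat shock genes, 2 rose and 11 fell (2 and 11 adjusted over the list alone) in OC.2+ against OC.2- cells (median -0.25, adjusted p = 0.00103, adjusted p = 0.245 with an estimated correlation), with Atf3, a stress-induced transcription factor, 4-fold lower. In OC.2- cells against adult hepatocytes 12 rose and 4 fell (13 and 4 adjusted over the list alone, camera adjusted p = 0.0563, and 0.0133 after median centring, 0.0205 after cyclic loess, 0.0271, 0.0173 and 0.0455 without adult replicate 2, adult replicate 3 and OC.2- replicate 2). In OC.2+ cells against adult hepatocytes 6 rose and 12 fell (7 and 12 adjusted over the list alone, camera adjusted p = 0.181, 0.0365 without adult replicate 1).

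Of the 19 measured Wnt targets and receptors, 0 rose and 10 fell (0 and 10 adjusted over the list alone) between OC.2+ and OC.2- cells (median -0.39, adjusted p = 0.000404). In OC.2+ cells against adult hepatocytes 3 rose and 11 fell (3 and 11 adjusted over the list alone), with median -0.68, adjusted p = 0.00174. The receptor Fzd4 was 8.19-fold and 10.2-fold lower in these comparisons, and in OC.2- cells against adult hepatocytes 5 rose and 9 fell (5 and 9 adjusted over the list alone), with median -0.18, adjusted p = 0.109. Of the 17 measured targets of YAP and TGF-beta, 2 rose and 13 fell (2 and 13 adjusted over the list alone) between the fetal groups (median -0.52, adjusted p = 0.000778, adjusted p = 0.118 with an estimated correlation), where the matrix signal Ccn1 was 6.27-fold lower and Tgfb1 2.87-fold higher. That list gave camera adjusted p = 0.286 in OC.2- and 0.138 in OC.2+ cells against adult hepatocytes. Of the 24 measured integrin and adhesion genes, 5 rose and 12 fell (5 and 12 adjusted over the list alone) between the fetal groups (median -0.27, adjusted p = 0.00447), with the neural cadherin Cdh2 5.69-fold lower and Cd47, a signal that restrains phagocytes, 3.17-fold higher. Against adult hepatocytes that list gave adjusted p = 0.911 in OC.2- cells and 0.176 in OC.2+ cells, where its median was 0.05, its mean -0.60 and camera pointed down. Of the 28 measured extracellular proteases and inhibitors, 5 rose and 14 fell (6 and 15 adjusted over the list alone) between the fetal groups (median -0.32, adjusted p = 0.0085, adjusted p = 0.101 with an estimated correlation). In OC.2- cells against adult hepatocytes 15 rose and 5 fell (15 and 5 adjusted over the list alone), with median 0.26, adjusted p = 0.0124, adjusted p = 0.121 with an estimated correlation, and the metalloproteinase inhibitor Timp1 was 10.9-fold higher. In OC.2+ cells against adult hepatocytes the list gave adjusted p = 0.532. Of the 25 measured lymphocyte genes, 11 rose and 0 fell (8 and 0 adjusted over the list alone) in OC.2+ cells against adult hepatocytes (median 0.21, adjusted p = 0.0348, adjusted p = 0.338 with an estimated correlation). This call ended after median centring (adjusted p = 0.0573), cyclic loess (0.0684), without adult replicate 3 (0.0502) and without OC.2+ replicate 2 (0.0528). The list gave adjusted p = 0.17 between the fetal groups and 0.107 in OC.2- cells against adult hepatocytes. Camera adjusted p for OC.2+ against OC.2- cells, OC.2- cells against adult hepatocytes and OC.2+ cells against adult hepatocytes was 0.0782, 0.33 and 0.755 for the Notch pathway, 0.889, 0.329 and 0.46 for cell cycle inhibitors and 0.368, 0.0823 and 0.49 for mesothelial genes. Median and mean differed in sign for the Notch pathway in OC.2+ cells against adult hepatocytes (0.05 and -0.03, camera down) and for mesothelial genes between the fetal groups (0.0035 and -0.22, camera down).

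At least 29 of 31 DNA replication genes and all 29 mitosis genes rose in each of the 3 comparisons. If dividing erythroid cells were the single source in both, the excess over adult intensity in OC.2+ cells, divided by that in OC.2- cells, would be alike for these genes and for erythroid genes. Among genes higher in OC.2- cells than in adult hepatocytes, the median ratio was 2.94 over 58 replication and mitosis genes, inside the interquartile range of 2.82 to 5.08 over 27 erythroid genes. With no such filter, which brings in 3 more erythroid genes, it was 2.97 over 60 genes, just outside a range of 2.98 to 5.24 over 30, so the test, which turned on the genes let in, decided nothing. Erythroid cells as the single source cannot be told apart from dividing hepatocytes, whose division rate is unknown. Other dividing cells and mixed sources were not tested. A ratio above 1 in 100% of the genes (58 of 58) restates that they were higher in OC.2+ cells and decides nothing.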
